A study of Homo sapiens with 3 samples.

How the data were processed

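The data were 3 lists of ChIP-seq regions from LNCaP cells, 1 each for CK2α with DHT, Pol II with DMSO and DHT, and Pol II with TBBz and DHT. Groups were taken from the treatment and antibody labels, because the source label is the same for both Pol II libraries and mentions TBBz in each. Whether the DMSO and TBBz libraries could have been exchanged was not checked by any value here. Per the labels, cells of passages 40 to 45 were grown in medium with 10% serum and moved to 5% charcoal-stripped serum before DHT. For CK2α the treatment label gives DHT for 2.5 hours while the protocol gives 90 min; which of these applies is not settled here. The vehicle is labelled as 25 μM DMSO.

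The submitters' processing notes name Bowtie for alignment, HOMER for peak calling and the build hg19; their versions are not given in the sources used here. Per the file headers, the authors called peaks separately in each library with HOMER in its factor style, centred, with a peak size of 200 bp, a minimum distance of 500 bp, a fragment length of 150 bp and a false discovery rate of 0.001, and the command names no control library. The tag threshold this gave was 12 for CK2α, 11 for Pol II with DMSO and 13 for Pol II with TBBz. Per the file headers, candidate peaks that did not stand 4-fold above the surrounding 10 kb were removed: 42856 of 56238 for CK2α, 25346 of 47165 for DMSO and 13517 of 38299 for TBBz. This setting is made for point-like binding, and it removes sites within broad Pol II signal, such as along a transcribed gene, so the lists say little about Pol II spread over gene bodies.

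The deposited columns hold the start and end of each region, its name, and a score per the authors that is 1 for every region and ranks nothing. Start coordinates, which count from 0 in the deposited lists, were raised by 1. Regions were 201 bp wide, except for 2 TBBz regions that were narrower (at least 142 bp). The number in a region's name counts candidates within a chromosome, and the place in the deposited list followed it closely (Spearman's rho of 0.981, 0.996 and 0.997 for CK2α, DMSO and TBBz). The place in the list was used in place of the score that had been planned, on the assumption that it follows strength. No tag value per region was at hand to test this; candidates with low numbers passed the comparison with their surroundings more often, from 95.5% in the first 10% to 21.1% in the last 10% with DMSO and from 47.0% to 14.8% for CK2α. That order carries no size, and places in lists of different lengths were not compared as a change.

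Depth is given by the file headers as 19021404, 15466579 and 22345614 tags for CK2α, DMSO and TBBz, with a mean of 23.5, 48.1 and 114 tags per region. A share of 10000 or more regions has a counting interval of about 1 percentage point to either side or less; tags of PCR copies are not independent, and with 1 library per group neither biological nor technical spread is known.

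Overlap meant at least 1 bp shared. Observed overlaps were compared with 1000 random placements of the same regions within the span of their chromosome that the lists cover, with 1000 circular shifts, and with 1000 shifts of each region by 10 to 50 kb. To compare Pol II regions with and without CK2α, regions without CK2α were drawn 10000 times at the same list positions, in 20 bins of order. Unshared regions of both Pol II lists were matched likewise by place after the longer list was shortened to the length of the other, a choice made after the data were seen. Regions were also counted in windows of 100 kb, and unshared regions were relabelled 1000 times between the lists. Intervals of shares are exact binomial (Clopper-Pearson), those of ratios are normal on the log scale, and those of median distances come from bootstrap draws of regions, all at 95%. The interval of the ratio of Pol II region numbers is an exception, converted from an exact binomial interval. Draws and placements describe these libraries and are not p-values. The scripts were tested on simulated data. For 13382 simulated CK2α regions, overlaps of 9.58%, 39.5% and 80.1% were recovered as 9.50%, 39.5% and 80.1%. For 21819 regions, order-matched differences of 0 and 10 percentage points were recovered as 1.05 and 9.57, in a single simulation each. A difference of about 1 point can therefore appear where none was made, and the spread of this error was not measured. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

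The comparisons, their tests, the alternative settings and the rule for named regions were fixed before the data were examined. The rule takes the 10 regions with the highest score per list and the 10 largest regions lost and gained; since the score is constant and widths are equal, it was applied as the first 10 regions of each list and the first 10 regions of each Pol II list with no overlap in the other. The regions with no partner within 2 kb, the CK2α regions far from Pol II and the 100 kb windows were added after the data were seen. The RefSeq gene table at hand is of GRCh38.p14 and was used only for the number of protein-coding genes per chromosome. An hg19 annotation was not used here, so the planned results that need one were not run: shares at promoters, in gene bodies and downstream of genes, gene-body coverage, its change in genes with and without CK2α, and the fixed gene lists. The comparison by CK2α was made between regions in their place, a choice made after the data were seen.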

Results

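LNCaP cells, an androgen-responsive human prostate carcinoma line, were held in hormone-depleted serum for 3 days and then given 100 nM dihydrotestosterone (DHT), the androgen that activates the androgen receptor. Chromatin immunoprecipitation sequencing (ChIP-seq), which recovers the DNA bound by a protein, was carried out on 1 library per group. One library was made with an antibody against CK2α, a catalytic subunit of the protein kinase CK2. The other 2 were made with an antibody against RNA polymerase II (Pol II), from cells that received the vehicle DMSO or 25 μM TBBz, a brominated benzimidazole that inhibits CK2. The labels of both Pol II libraries include a source name that mentions TBBz, and they are told apart here by their treatment labels; an exchange of the libraries would turn every gain into a loss. Both Pol II cultures were treated for 2.5 hours, with DHT present for the last 1.5 hours. The libraries held 19021404 tags for CK2α, 15466579 for Pol II with DMSO and 22345614 for Pol II with TBBz. There were no replicates, so no difference between the libraries could be set against a spread between replicates and no test between conditions was made. Intervals of shares are exact (Clopper-Pearson) 95% binomial intervals, and those of ratios are 95% normal intervals on the log scale. The interval of the ratio of Pol II region numbers is instead converted from an exact binomial interval, as if the 2 lists were independent. All of these intervals cover counting error only. All positions are in hg19.

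The first question was where CK2α binds in the genome. The CK2α list held 13382 regions, which covered 2.69 Mb. Chromosome 19 was the most densely bound, with 13.9 CK2α regions per Mb, followed by chromosome 17 with 9.04 and chromosome 22 with 8.14. Chromosome X carried 1.86 regions per Mb and chromosome Y carried 1.03, the lowest density of the 24 chromosomes. Pol II was distributed in the same manner, with 25.4 regions per Mb on chromosome 19 and 1.33 on chromosome Y in the DMSO library. Across the 24 chromosomes the density of CK2α regions followed the number of protein-coding genes per Mb (RefSeq genes of GRCh38.p14), with Pearson's r = 0.971 and Spearman's rho = 0.921. Without chromosomes 19 and Y, r was 0.932. For Pol II, r was 0.982 with DMSO and 0.977 with TBBz. Chromosomes are not replicates, and no p-value was drawn from these coefficients.

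**Figure D1:**
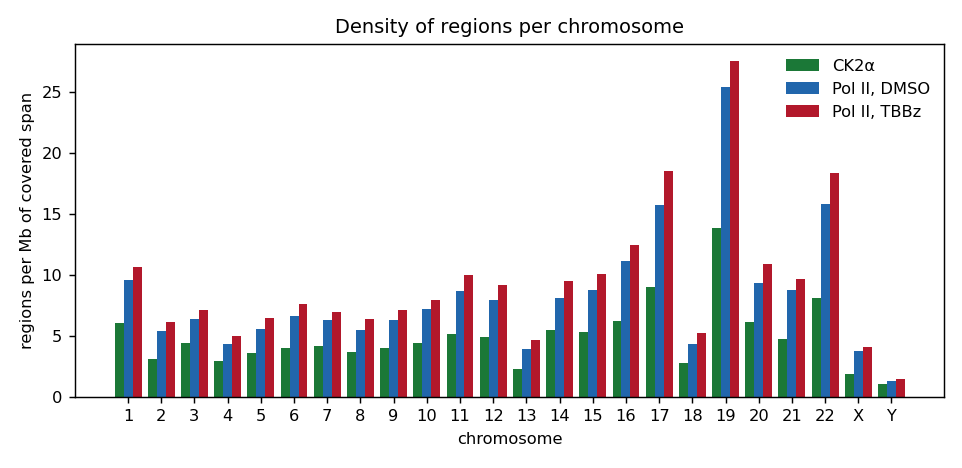
Regions per Mb of covered span (vertical axis) for each chromosome (horizontal axis), with bars for the CK2α, Pol II DMSO and Pol II TBBz lists, 1 library each. Chromosome 19 has the tallest bars, with 13.9, 25.4 and 27.5 regions per Mb, and chromosome Y the shortest.

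CK2α lay close to Pol II. Of the 13382 CK2α regions, 4929 overlapped a Pol II region of the DMSO library by at least 1 bp, which is 36.8% (95% interval 36.0 to 37.7%). Randomly placed regions gave a mean of 47.5 overlaps and at most 77 in 1000 placements, so the observed number was 104 times the mean placement. When each region was instead moved by 10 to 50 kb, which keeps it in its own neighbourhood, the observed number was 44.8 times the mean. A further part of the CK2α regions lay near a Pol II region without overlapping it: 66.8% of all CK2α centres were within 500 bp of a DMSO Pol II centre, 78.3% were within 1 kb and 21.7% were farther away. Among pairs within 1 kb the median distance between the centres was 219 bp (quartiles 91 and 390 bp), against 24 bp (quartiles 10 and 73 bp) between the DMSO and TBBz Pol II lists. In the reverse direction, 22.6% of the DMSO Pol II regions overlapped a CK2α region and 47.5% had a CK2α centre within 1 kb. A total of 3866 CK2α regions (28.9%) overlapped both Pol II lists and 7503 (56.1%) overlapped neither. The CK2α regions held 1.65% of the tags of their library, against 6.79% for Pol II with DMSO, and no control library was used. Neither random placement nor shifts of 10 to 50 kb can separate CK2α binding from background that piles up at Pol II sites.

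**Figure D2:**
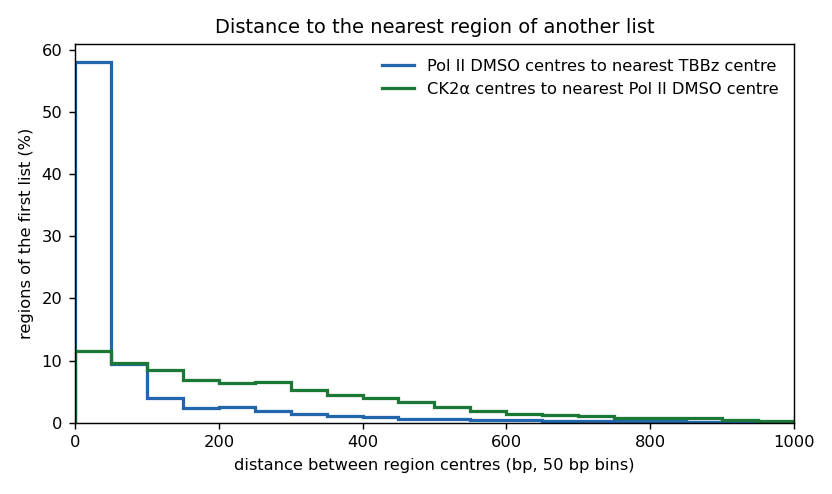
Share of regions (vertical axis, percent) by distance to the nearest centre of another list (horizontal axis, bp, in bins of 50 bp), for CK2α against Pol II DMSO and for Pol II DMSO against Pol II TBBz. The distances between the Pol II lists pile up in the first bin, whereas 11.6% of the CK2α regions fall there and the rest spread over longer distances.

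The leading CK2α regions coincided with Pol II regions. The 10 regions that open the CK2α list included chr21:9826038–9826238, chr1:156186299–156186499, chr1:91852874–91853074, chr1:121484763–121484963 and chr20:26190024–26190224, and 9 of the 10 had a Pol II centre of both libraries within 200 bp. The exception was chr11:66189155–66189355, whose nearest Pol II centre was 17018 bp away with DMSO and 16983 bp away with TBBz. The loci of chr21:9826038–9826238, chr1:156186299–156186499, chr1:121484763–121484963 and chr1:149223774–149223974 stood among the first 10 of both the CK2α and the DMSO Pol II list. In the first 10% of the CK2α list 57.4% of regions overlapped DMSO Pol II (54.7 to 60.1%), and in the last 10% it was 22.9% (20.7 to 25.3%). Across the 4929 overlapping pairs the positions in the CK2α and DMSO lists had a Spearman's rho of 0.517, across regions of single libraries. The lists were called without a control library, and 4 of the first 10 CK2α regions lay within 1 Mb of a stretch of at least 2 Mb that holds no region, as did 1 of the first 10 DMSO regions and 0 of the first 10 TBBz regions. For CK2α the share was 11.8% in the first 1000 regions and 10.5% in the whole list. Without a control library, the coincidence of leading CK2α and Pol II regions cannot be told apart from background shared by the libraries.

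The second question was how Pol II binding differed between cells given the CK2 inhibitor TBBz and cells given DMSO. TBBz was the only means of inhibiting CK2 here, so loss of CK2 activity cannot be told apart from other effects of the compound. With TBBz the Pol II list held 24782 regions (4.98 Mb), against 21819 (4.39 Mb) with DMSO, a ratio of 1.14 (1.12 to 1.16). The TBBz library was the deeper one, and divided by the library totals the ratio of region numbers was 0.786. This scaling takes region numbers to grow in proportion to depth, and tags were not subsampled to test that. The direction of the difference at equal depth is therefore not settled. The excess in number was found on each of the 24 chromosomes, from a ratio of 1.08 on chromosome X to 1.20 on chromosome 18. Pol II tags were more concentrated in the called regions with TBBz: they held 12.6% of all tags, against 6.79% with DMSO, and the mean region held 114 tags, against 48.1. Scaled to equal library totals, the ratio of tags per region was 1.63. The number of candidate peaks was lower with TBBz, at 38299 against 47165. Of these candidates, 35.3% with TBBz (34.8 to 35.8%) and 53.7% with DMSO (53.3 to 54.2%) were removed because they did not stand 4-fold above the surrounding 10 kb. A site missing from a list is therefore not necessarily a site without Pol II: it can also be a site with much Pol II around it.

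Most Pol II sites were shared between the conditions. Of the DMSO regions, 16112 overlapped a TBBz region, which is 73.8% of the DMSO list (73.3 to 74.4%) and 65.0% of the TBBz list (64.4 to 65.6%), 178 times the mean of random placements and 74.3 times that of placements within 10 to 50 kb. Their positions in the lists had a Spearman's rho of 0.895. The shares fell along the lists, from 92.4% in the first 10% of the DMSO regions to 35.7% in the last 10%, and from 90.0% to 20.6% for the TBBz regions. The leading regions were nearly all shared: the first 10 of each Pol II list had a partner centre within 200 bp, among them chr1:149223844–149224044, chr17:41438528–41438728 and chr19:18392259–18392459 of the DMSO list. Of the first 10 DMSO regions with no TBBz overlap, 9 had a TBBz centre between 206 and 504 bp away, for example chr1:45196656–45196856 and chr1:155532974–155533174, and all of the first 10 TBBz regions with no DMSO overlap had a DMSO centre between 256 and 504 bp away.

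**Figure D3:**
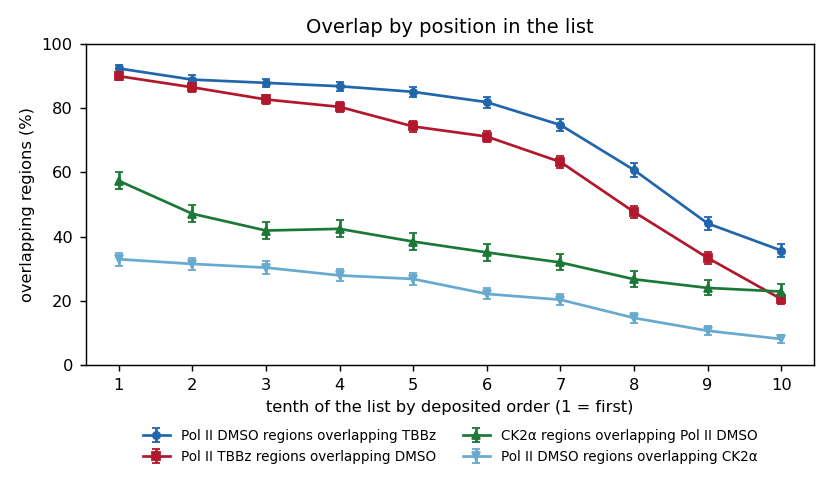
Share of regions that overlap another list (vertical axis, percent; bars are exact 95% binomial intervals) by position in the deposited list, in 10 equal parts from the first to the last (horizontal axis). Overlap between the Pol II lists falls from 92.4% to 35.7% of DMSO regions and from 90.0% to 20.6% of TBBz regions, and the overlap of CK2α with Pol II DMSO falls from 57.4% to 22.9%.

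Sites found in 1 condition with no partner within 2 kb numbered 3042 with DMSO (13.9%) and 5236 with TBBz (21.1%), and they stood late in their lists, at a median of 86.7% and 84.1% of the list. Among the first 10000 regions they numbered 45 with DMSO and 174 with TBBz. The first such DMSO region was chr19:51364817–51365017, at place 172. In the 60 kb around it, chr19:51340001–51400000, no DMSO region overlapped a TBBz region. DMSO regions also stood at chr19:51383399–51383599 and chr19:51393715–51393915, and TBBz regions at 6 other positions, including chr19:51358145–51358345. CK2α had 4 regions in this stretch. Among them, 1 lay 30 bp from the DMSO region at 51383399, and chr19:51393558–51393758 overlapped the DMSO region at 51393715. The first TBBz regions with no DMSO region within 2 kb were chr16:730369–730569, chr1:154973437–154973637, chr16:1823039–1823239 and chr10:134210441–134210641. None of the first 10 such TBBz regions had a CK2α centre within 1 kb, against 3 of the first 10 DMSO regions with no TBBz region within 2 kb, which included chr19:676284–676484 and chr19:2273721–2273921.

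In a small number of 100 kb windows, regions called with TBBz and not with DMSO stood in strings. The 100 kb window with the largest excess was chr11:114000001–114100000, with 12 TBBz regions, no DMSO region and no CK2α region; the TBBz regions stood between places 9032 and 17031 of their list. The window before it, chr11:113900001–114000000, had 10 TBBz, 3 DMSO and 4 CK2α regions. Next came chr18:55900001–56000000 with 11 TBBz regions and none of the other lists, chr2:189100001–189200000 with 11 TBBz and 3 DMSO regions, and chr14:30200001–30300000, chr15:89600001–89700000, chr6:34500001–34600000 and chr8:102500001–102600000, each with 10 TBBz and 2 DMSO regions. In the opposite direction, chr21:22400001–22500000 had 9 DMSO and 3 TBBz regions and chr4:167100001–167200000 had 5 DMSO regions and none with TBBz. Losses of this size were no more frequent than in relabelled lists: 865 of 1000 random relabellings of the unshared regions gave as many windows with a DMSO excess of at least 5, and 622 gave as large an excess. An excess of at least 5 TBBz regions was found in 56 windows and an excess of at least 5 DMSO regions in 3; with equal numbers of regions from both lists the counts were 38 and 5. When the unshared regions were relabelled at random 1000 times, 22 relabellings gave as many TBBz-only windows as the 55 counted in that way (mean 42.9), and 19 gave a window with as large an excess. These windows were chosen after their values were seen. Another TBBz region lay within 10 kb of 42.5% of the shared TBBz regions and of 48.8% of the TBBz regions with no DMSO overlap. For those with no DMSO region within 2 kb it was 38.5%, so the direction depended on the definition of a TBBz-only region.

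**Figure D4:**
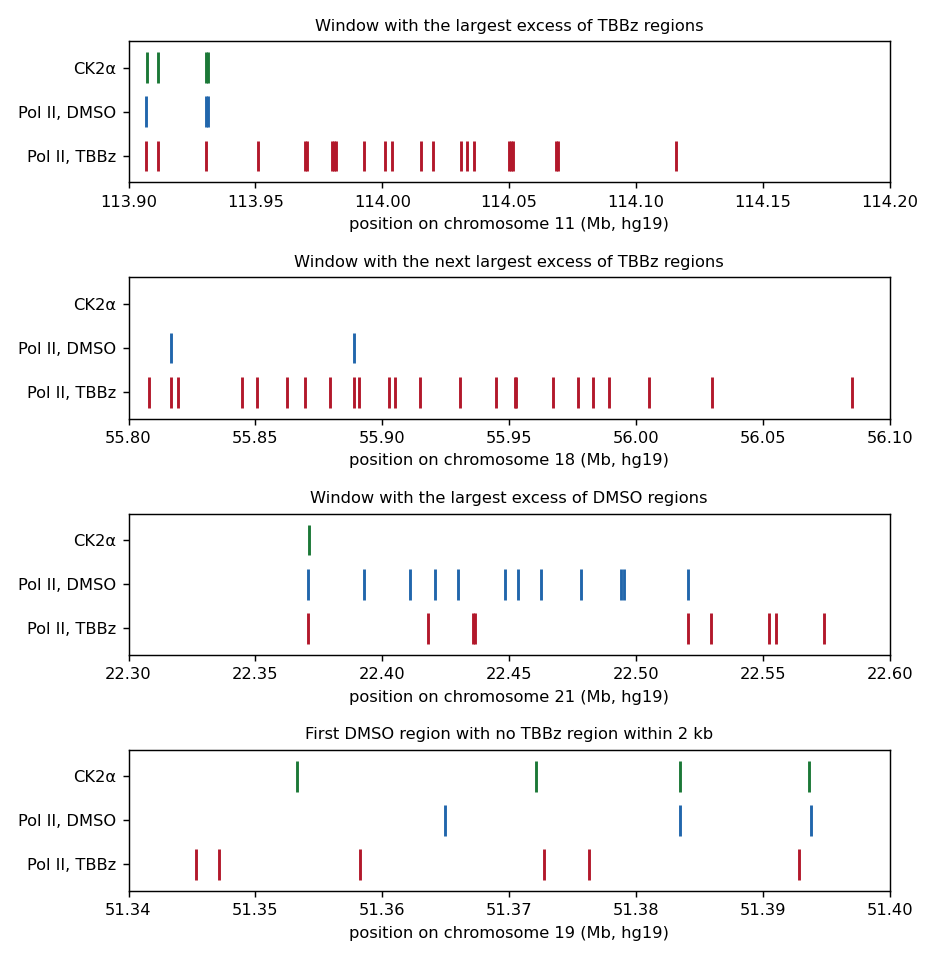
Positions of CK2α, Pol II DMSO and Pol II TBBz regions (vertical lines, 1 row per list) along 4 stretches of chromosomes 11, 18, 21 and 19 (horizontal axes, Mb, hg19). On chromosome 11 the window from 114.0 to 114.1 Mb holds 12 TBBz regions and no DMSO region, and on chromosome 21 the window from 22.4 to 22.5 Mb holds 9 DMSO and 3 TBBz regions.

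The third question was whether Pol II sites with CK2α responded differently to TBBz from those without. DMSO Pol II regions that overlapped CK2α were found again with TBBz in 81.2% of cases (80.1 to 82.3%), and those without CK2α in 71.7% (71.0 to 72.4%). CK2α-overlapping regions stood earlier in the list, and regions without CK2α drawn at the same positions were found again in 80.6% of cases, a difference of 0.641 percentage points, which 1108 of 10000 draws matched or exceeded. This difference changed sign with the definition. It was −2.14 points when CK2α was counted within 1 kb and −3.63 points in the upper 50% of each list. It was 1.11 points when CK2α was counted within 1 kb and a TBBz region within 2 kb counted as found again. For the 1.11 points 0 of 10000 draws were as high, and for the −2.14 points 0 of 10000 were as low. The positive values lie near the 1.05 points recovered in a single simulation of a difference of 0, which does not give the spread of that error. The values of −2.14 and −3.63 points are larger in size than 1.05 but were not found with the other definitions. Whether Pol II regions with CK2α were missing from the TBBz list more often is therefore not settled.

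Regions called only with TBBz were poor in CK2α. The TBBz library was deeper and had more of its tags in regions. A region called only with TBBz may therefore be a site that also held Pol II with DMSO but was missed in that library. Of the TBBz regions that overlapped CK2α, 84.0% were also called with DMSO (83.0 to 85.1%), against 60.4% of those without CK2α. For TBBz regions without CK2α at the same list positions it was 72.5%, and none of 10000 draws reached 84.0%. Of the regions in the TBBz list alone, 8.87% overlapped CK2α (8.28 to 9.49%), against 16.2% of those in the DMSO list alone (15.3 to 17.2%) and 24.9% of the shared DMSO regions. Shared DMSO regions stood earlier, at a median of 41.6% of their list, against 77.8% for DMSO-only and 74.9% for TBBz-only regions. CK2α overlap itself fell along the TBBz list, from 29.1% in the first 10% to 6.13% in the last 10%. For regions with no partner within 2 kb the shares were 4.24% with TBBz (3.71 to 4.82%) and 11.5% with DMSO (10.4 to 12.7%), a ratio of 2.71. The ratio was smaller over all unshared regions, at 1.83. It was 1.52 with equal numbers of Pol II regions and 1.46 with CK2α counted within 1 kb. The CK2α library came from cells without inhibitor, and CK2α binding with TBBz was not analysed here.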

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

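The local shift, the removal of regions near region-free stretches, the CK2α distance of 1 kb and the partner distance of 2 kb, alone and together, were chosen after the data were seen; the other alternatives were planned. No alternative brought either overlap near that of random placement, the ratio of CK2α shares between DMSO-only and TBBz-only regions stayed above 1 (1.46 to 2.71), and TBBz regions with CK2α stayed more often present with DMSO than order-matched regions (by 7.28 to 12.6 points). The matched difference in DMSO regions kept with TBBz did not keep its sign (−3.63 to 1.31 points). Its positive values lie near the 1.05 points recovered in a single simulation of a difference of 0. A wider overlap rule also lets random regions overlap more often, which lowers the folds by construction; the cause of the other changes was not tested. Limiting the lists to chromosomes 1 to 22 and X and using circular shifts moved no value beyond its counting interval. The alternatives that need a gene annotation (promoter widths, all annotated genes, matching on gene length, CK2α in gene bodies) were not run, and with equal numbers the ratio of Pol II region numbers is 1 by construction. No paired analysis was possible because each group has 1 library. Sharing was lowest at the ends of the lists; tags were not subsampled, so what depth limits there was not tested.

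With centres within 500 bp, CK2α overlap with DMSO Pol II was 66.8% (76.5-fold over random placement), and the Pol II lists shared 82.1% of DMSO and 72.3% of TBBz regions (81.1-fold). With an overlap of 50% of the shorter region these were 21.4% (120-fold), 67.7% and 59.6% (325-fold), the matched differences were −0.0331 points for DMSO and 12.6 points for TBBz regions, and the rho of order was 0.890. With regions extended by 1 kb they were 80.8% (22.5-fold), 86.1% and 79.1% (21.3-fold), with a ratio of CK2α shares of 2.57, a TBBz matched difference of 9.64 points and a rho of 0.888. With regions within 1 kb merged they were 44.2% (99.0-fold), 76.0% and 68.1% (147-fold), and the ratio of region numbers was 1.11.

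In the upper 50% of each list there were 6691 CK2α regions, of which 35.5% overlapped DMSO Pol II (188-fold). The Pol II lists then shared 83.0% and 73.0% (364-fold), the ratio of CK2α shares was 2.17, the matched differences were −3.63 and 8.20 points and the rho was 0.684. With equal numbers of Pol II regions the lists shared 70.9% of either list (193-fold), the ratio was 1.52 and the rho 0.886. Against local shifts the folds were 44.8 for CK2α and 74.3 for the Pol II lists. Without regions near region-free stretches the Pol II fold was 185 and the DMSO matched difference −0.236 points. With CK2α counted within 1 kb the ratio was 1.46 and the matched differences were −2.14 and 7.28 points. With partners counted within 2 kb the ratio was 2.71 and the TBBz matched difference 7.53 points; with both distances together they were 2.71 and 9.37 points.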

Other observations

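The tests of explanations in this part were chosen after the results were seen. The setting of equal numbers of Pol II regions was planned, but the comparison of CK2α shares to which it was applied was not. A minority of CK2α regions stood apart from the called Pol II regions: 1578 (11.8%, 11.3 to 12.4%) had no Pol II centre of either library within 10 kb. Sites within broad Pol II signal were removed from the lists, so Pol II may still be present at these CK2α regions. The 1578 regions were mostly late in the list, with 29 among the first 1000 and 324 among the last 1000. The early ones included chr11:66189155–66189355, chr19:51297700–51297900, chr4:1404302–1404502, chr19:57149417–57149617 and chr9:128845059–128845259, the last 178 kb from the nearest called Pol II region. Such regions made up 5.40% of the CK2α regions on chromosome 19 (3.95 to 7.18%) and 16.6% on chromosome 3 (14.2 to 19.2%). Pol II regions were denser on chromosome 19, at 25.4 per Mb with DMSO against 6.35 on chromosome 3, which by itself makes such CK2α regions rarer there. These shares were not compared with random placements. The 100 kb window with most CK2α regions was chr16:33900001–34000000 with 12, where Pol II had 9 with DMSO and 8 with TBBz. It was followed by chrY:13800001–13900000, chr17:45200001–45300000 and chr16:46400001–46500000 with 10 each. In these 3 windows Pol II had 11, 10 and 9 regions with DMSO and 13, 10 and 10 with TBBz. At chr4:190800001–190900000 there were 9 CK2α regions and 3 in each Pol II list. The lists were called without a control library, so CK2α binding in such windows cannot be told apart from background shared by the libraries.

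The share of Pol II regions with no partner within 2 kb varied between chromosomes in these single libraries. The chromosomes named here were picked by their values among the 24. The intervals treat regions as independent, whereas on chromosome 21 some stood in strings, such as the 9 DMSO regions in chr21:22400001–22500000. On chromosome 21, 22.9% of DMSO regions (18.5 to 27.8%) had no TBBz region within 2 kb, against 13.9% over all chromosomes, and 26.4% of TBBz regions had no DMSO region, against 21.1%. Chromosome 18 had the highest share of such TBBz regions, 27.4% (23.1 to 32.0%), and chromosomes X and 19 the lowest, 14.5% (11.8 to 17.5%) and 15.5% (13.8 to 17.3%).

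With TBBz a larger share of Pol II tags fell into called regions than with DMSO (12.6% against 6.79%). Greater sequencing depth should give more candidate peaks, but the ratio of candidates was 0.812 (0.801 to 0.823), which argues against depth as the whole cause. Open are a more efficient immunoprecipitation with TBBz, which fits the kept order of shared regions (rho of 0.895), and Pol II drawn from broad signal into narrow sites by the inhibitor, which fits the smaller share of candidates removed against their surroundings (a ratio of 0.657 to DMSO). No value here excludes either, and with 1 library per condition they cannot be told apart. The second may be looked at in read coverage along genes, which was not analysed here.

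Regions in the TBBz list alone overlapped CK2α less often than those in the DMSO list alone (8.87% against 16.2%). With equal numbers of regions the ratio of the shares fell from 1.83 to 1.52 (1.38 to 1.66). In these shortened lists TBBz-only regions stood earlier than DMSO-only regions, at a median place of 15892 against 17233. CK2α overlap fell along the lists, so the lower ratio does not show that list length accounts for part of the difference. Place in the list does not account for it: TBBz-only regions at the places of the DMSO-only regions had a share of 9.38% in lists of equal length. The DMSO-only share was 15.9% (15.0 to 16.8%), which 0 of 10000 draws reached. Small shifts of a site and pile-ups beside region-free stretches do not either: the ratio of the shares was 2.71 (2.31 to 3.19) with partners within 2 kb left out and 1.91 (1.74 to 2.10) without regions near such stretches. Background shared by the more weakly enriched CK2α and DMSO libraries was not tested and stays open without a control library, as does the fact that CK2α was measured without inhibitor. With CK2α counted within 1 kb the shares were 23.8% and 34.7%, and no biological explanation was tested.

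CK2α centres lay a median of 219 bp from the nearest DMSO Pol II centre within 1 kb, against 24 bp between the Pol II lists. Imprecise centres of weak regions alone do not give this, if place in the list follows strength: the last 5% of DMSO regions lay a median of 65 bp from TBBz centres (bootstrap interval 57 to 76 bp), below the 184 bp (174 to 192 bp) of the first 25% of the CK2α list. A broad CK2α signal without a sharp maximum stays open, since 76.2% of CK2α candidates were removed for not standing above their surroundings. A candidate explanation on the biological side, that CK2α sits beside Pol II, was not tested. The position of CK2α relative to gene starts was not analysed here.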
